A study of Arabidopsis thaliana with 4 samples.

How the data were processed

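RNA from 2 whole-root and 2 sorted-protoplast samples was amplified in 2 cycles, labelled with biotin and hybridized to Affymetrix ATH1 arrays, per the labels. The deposited values are signal intensities on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. On each array the trimmed mean of the deposited intensities (2% left out at each end) was 250.02, so each array had been scaled to the same level by the authors. MAS5 values spread widely at low signal, which the offset and the filter below address. Groups and replicate numbers came from the sample titles, and 0 columns of the table were left unmapped. No probe set had the same value on both arrays of a group.

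The table holds 22810 probe sets, of which 64 are controls. Names came from the platform annotation, updated through gene identifiers to the symbols of the TAIR10.1 RefSeq gene table. Of the 22746 others, 13513 had 1 gene, 503 had several and 8730 were not listed there and are unnamed here. Of those with 1 gene, 13436 matched the RefSeq table. Many well-known genes are among the unlisted, which kept most fixed lists from being tested. Genes of the plastid genome were taken from the RefSeq table, and those of the mitochondrial genome from the platform's gene names where the RefSeq table held no such gene. The arrays cannot separate mitochondrial transcripts from those of near-identical nuclear copies. No genome coordinates are given, since no build is named for the array's design.

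Signals were transformed as log2(signal + 16), with the authors' scaling kept, so differences of low-signal genes are understated. Control probe sets and the 40% of the others with the lowest mean log2 value were left out, which left 13647, with a filter at a signal of about 51.3. Differences between sorted protoplasts and whole roots were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trended prior variance), with 2 residual and 7.56 prior degrees of freedom. The adjusted p is Benjamini-Hochberg's, with a threshold of 0.05. Log2 differences are sorted protoplasts minus whole roots, and their SE is the moderated one.

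Before the data were examined, 21 gene lists were fixed, except that the cytosolic ribosomal protein list was left to be filled from the reference tables. The other lists held 466 distinct genes. The ribosomal list was planned from gene descriptions but was filled from gene synonyms, with 44 genes. 4 entries were dropped because their symbol did not match the locus. Of the listed genes 53 had a probe set with a single gene name and 42 were tested. 8 lists had 0 tested members, 9 had 1 to 4, and 4 had the 5 needed for a list test. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way and not whether they differ from other genes. Of the 4 lists, 2 were higher and 0 lower with camera, and 0 held with an estimated correlation. The estimate rests on 2 residual degrees of freedom, so that test has little power here. A call lost in it is weak evidence against a list. After the annotation had been seen, 39 more lists were tested as one family: plastid genes, mitochondrial genes, nuclear genes with an osmotic, drought, salt, cold or abscisic acid name, and gene families by symbol with at least 5 tested nuclear genes.

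The genes named were set by a rule fixed beforehand: the 5 highest and 5 lowest log2 differences among probe sets past the threshold whose single gene has a symbol, and for each list the member with the largest rise and the one with the largest fall among those past the threshold, or the 2 largest where all went one way, or the 2 brightest where none passed. Where several tested probe sets matched a gene, the brightest stood for it. Other list members, the 5 highest nuclear genes with a symbol, members of the added lists and neighbouring genes are named in addition, chosen after their values were seen.

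Alternatives were other offsets, filters, array scalings, prior variances, thresholds and list tests, a replicate block, the removal of probe sets that share probes, and each array left out in turn. With an array left out, a group of 1 is assumed to vary like the other. Added after seeing the data were scaling on the 18 hybridization spike-in probe sets, the removal of organelle probe sets and crossed replicate numbers. On simulated data of 13647 probe sets with the fitted variances and 2000 of them changed, the test for sorted protoplasts against whole roots called on average 20.8% of changes of 1 on the log2 scale, 91.4% of changes of 2 and 99.6% of changes of 3, and 4.11% of its calls were of unchanged probe sets. With 200 changed, it called 1.4%, 54.4% and 97.0% of changes of these sizes. The simulated noise was normal and independent between probe sets, as the test assumes, so these shares need not hold for the data. Figures were drawn with matplotlib 3.10.9.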

Results

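Transcript levels were measured on 4 Arabidopsis ATH1 arrays, 2 for each of 2 preparations of Columbia seedling roots taken 6 days after germination. All roots had been moved to medium with 140 mM NaCl for 1 hour. In the first group RNA came from intact roots, here called whole roots. In the second group the root cell walls were digested to release protoplasts, which were run through a cell sorter with every cell kept, here called sorted protoplasts. The comparison asks how much protoplasting and sorting change transcript levels, with genes that respond to salt as the series' stated interest, and there is no array of untreated roots among the 4. The median signal was 82.3 and 90.2 on the whole-root arrays and 80.7 and 79.0 on the sorted-protoplast arrays. Across the 13647 probe sets tested, Pearson's r of log2 signals was 0.938 between the whole-root arrays, 0.910 between the sorted-protoplast arrays and 0.768 to 0.790 across groups, where probe sets are not independent replicates. The number of arrays limits the precision of every value, and because the labels do not say that replicates came from separate plantings, p-values measure only the spread between these samples, which may be technical.

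Few genes of the salt and osmotic stress lists fixed beforehand could be measured, and those tested did not pass. Of the 38 abscisic acid (ABA) and osmotic stress genes listed, 3 were tested, and 0 rose or fell in limma's test, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05. COR47, a dehydrin, had a signal of 13032 ± 1067 in whole roots and 14371 ± 2477 in sorted protoplasts (SD, n = 2), a log2 difference of 0.13 with a 95% interval from -0.60 to 0.87. LTI30, another dehydrin, had a log2 difference of -0.13 (95% interval -0.89 to 0.63), and LEA4-5, a late embryogenesis abundant protein gene, had one of -0.47 (95% interval -1.30 to 0.36). These intervals do not exclude changes of well over 0.5 on the log2 scale. COR47 was the brightest probe set on the array of whole-root replicate 2, at 12277.3, and so lay at the top of the range measured there. On whole-root replicate 1, where the highest signal was 14482.8, COR47 had 13786.1 and LTI30 13559.1, so LTI30 also lay near the top. COR15A and COR15B were below the signal filter, and the other listed genes had no probe set with a single gene name. The 16 sodium and potassium transport genes had 0 tested members. A list added later held 13 nuclear genes with an osmotic, drought, salt, cold or abscisic acid name. Of these 10 did not pass, 2 rose, STZ (2.56 ± 0.39) and COR27 (1.36 ± 0.36), and 1 fell, OSM34 (-2.13 ± 0.51).

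Transcripts of the plastid genome were higher in sorted protoplasts. Of 62 tested plastid genes 57 rose and 0 fell, with a mean log2 difference of 2.83. Among genes with a symbol and not only a locus number, the 5 with the highest differences were rpl14 and rpl36 (plastid ribosomal proteins), psaI (a photosystem I subunit), atpF (a plastid ATP synthase subunit) and the nuclear gene JRG21, a jasmonate-regulated oxygenase. The signal of rpl14 was 46.7 ± 18.1 in whole roots and 2608 ± 1775 in sorted protoplasts (SD, n = 2), a log2 difference of 5.23 ± 0.50 (SE, limma adjusted p = 0.000516). The differences were 4.68 ± 0.63 for JRG21, 4.54 ± 0.45 for psaI, 4.54 ± 0.52 for rpl36 and 4.49 ± 0.52 for atpF. Of 11 tested genes of the mitochondrial genome 9 rose and 0 fell, with a mean log2 difference of 2.51, led by cox1 (a cytochrome oxidase subunit) at 3.97 ± 0.55 and ccb382 at 3.14 ± 0.57. Both organelle lists, added after the annotation had been seen, passed limma's camera test with its preset correlation (adjusted p = 1.12e-44 and 4.65e-09). Neither call held with an estimated correlation (adjusted p = 0.967 for each). That test rests on 2 residual degrees of freedom and has little power here. The estimates were 0.690 and 0.876, against the preset 0.01, so the preset p-values treat members that moved together as nearly independent. The sorted-protoplast arrays had mean log2 signals of 9.56 and 10.61 for plastid and 7.82 and 9.53 for mitochondrial probe sets. The whole-root arrays had 7.44 and 7.07, and 6.53 and 6.09. The mean of the plastid list stayed between 2.31 and 3.36 when any single array was left out. Fits without a whole-root array take their spread from the sorted-protoplast arrays alone. Fewer plastid genes were called higher in them than in fits without a sorted-protoplast array. Of the 14 mitochondrial probe sets tested 10 were called higher. Here too fewer were called higher without a whole-root array than without a sorted-protoplast array. The mean of the mitochondrial list lay between 1.70 and 3.31 when any single array was left out.

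Of the 38 early wound and touch response genes listed, 7 were tested. Of these 6 rose in sorted protoplasts, over all genes and adjusted over the list alone, and the mean log2 difference was 2.97. AT1G76640, a calmodulin-like gene listed as CML39, went from 3.44 ± 0.55 to 1145 ± 858 (SD, n = 2), a log2 difference of 5.67 ± 0.51 (SE, limma adjusted p = 0.000391). That gene's whole-root signal was below the offset of 16, so its log2 difference understates the ratio. CML38, its neighbour and also calmodulin-like, rose by 4.06 ± 0.41, the ubiquitin ligase genes PUB23 and PUB22 by 3.21 ± 0.51 and 2.79 ± 0.49, the zinc finger gene STZ (ZAT10) by 2.56 ± 0.39 and WRKY53 by 1.99 ± 0.36. PUB24 had a difference of 0.47 ± 0.41, which did not pass. The list passed camera's test at the preset correlation (adjusted p = 2.02e-08). That call was lost with the estimated correlation of 0.697 (adjusted p = 0.274) and in fry (adjusted p = 0.0535). As with the organelle genes, fewer members were called higher without a whole-root array than without a sorted-protoplast array.

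**Figure D1:**
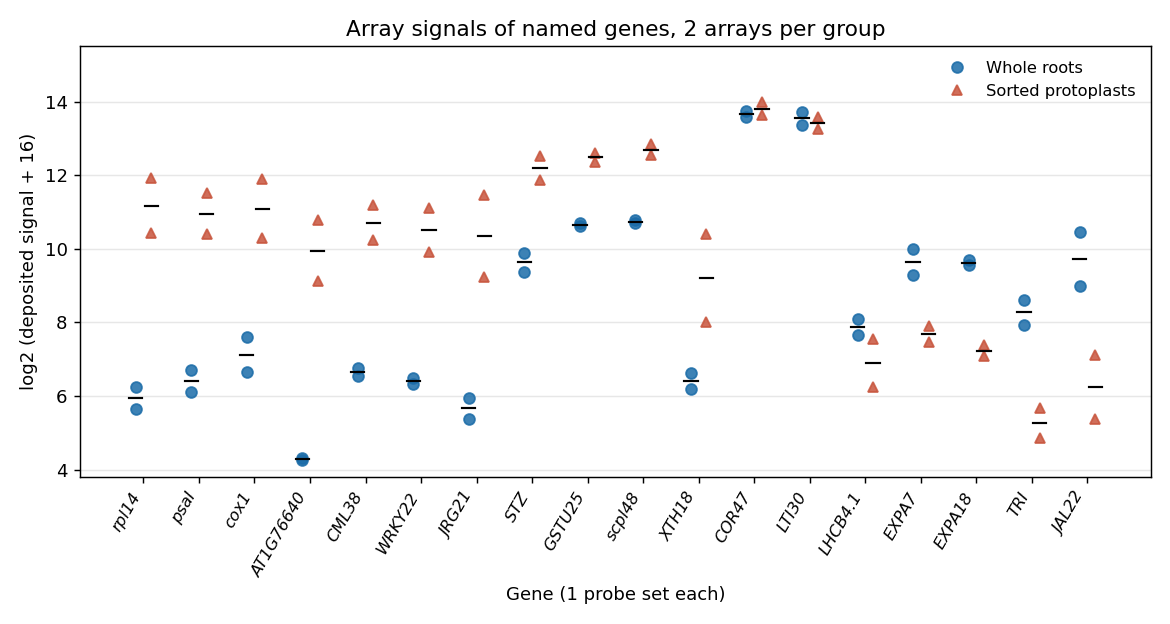
Log2 of the deposited signal plus 16 (vertical axis) for 18 named genes (horizontal axis), with 1 circle per whole-root array, 1 triangle per sorted-protoplast array and a black line at each group's mean. The organelle genes rpl14, psaI and cox1 and the genes from AT1G76640 to XTH18 lie higher on both sorted-protoplast arrays, COR47 and LTI30 overlap near the top of the scale, and EXPA7, EXPA18, TRI and JAL22 lie lower.

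Detoxification genes rose in part, and the 5 tested members of the detoxification and oxidative stress list were all glutathione transferase (GSTU) or glycosyltransferase (UGT) genes. Among the lists added later, neither family passed camera's test. The mean was 0.12 for 8 GSTU genes (adjusted p = 0.927) and -0.10 for 35 UGT genes (adjusted p = 0.954). Of 5 tested members 2 rose, or 4 adjusted over the list alone. GSTU25, a glutathione transferase gene, rose by 1.83 ± 0.34 (adjusted p = 0.00943) and UGT73B4, a glycosyltransferase gene, by 1.60 ± 0.37 (adjusted p = 0.0239). GSTU26 had a difference of -0.71 ± 0.38, which did not pass. The list's mean was 0.99 (camera adjusted p = 0.0109). That call was lost with an estimated correlation (adjusted p = 0.274), in fry (adjusted p = 0.0535) and without sorted-protoplast replicate 2 (mean 0.80, camera adjusted p = 0.0726).

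Wall remodelling genes moved both ways. Of 5 tested expansin and XTH genes 2 rose and 2 fell, also adjusted over the list alone. XTH18 and XTH20, xyloglucan endotransglucosylase/hydrolases, rose by 2.80 ± 0.65 and 1.74 ± 0.40. EXPA18 and EXPA7, expansins of root hairs, had differences of -2.39 ± 0.35 (adjusted p = 0.00301) and -1.95 ± 0.39 (adjusted p = 0.0135). The list did not pass (mean 0.12, camera adjusted p = 0.849), its mean was -0.32 with spike-in scaling, and fry, which gave the opposite sign to the mean, did not pass either. Of 2 tested wall polysaccharide synthesis genes, CSLC04, a xyloglucan backbone synthase, rose by 2.14 ± 0.40, and COB had a difference of -0.37 ± 0.41. Of 5 auxin genes 1 rose, LBD16, a regulator of lateral root initiation, by 1.75 ± 0.36, and adjusted over the list alone 2 rose and 1 fell. The auxin list did not pass (mean 0.44, camera adjusted p = 0.250), but its mean was 1.06 without sorted-protoplast replicate 2 (camera adjusted p = 0.0213) and -0.18 without sorted-protoplast replicate 1.

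Lists of markers for root cell types had few tested members, and none of them had the 5 needed for a list test. The 2 root hair markers tested were EXPA7 and EXPA18, which both fell. Both root cap and cell death markers tested rose, the aspartic protease gene AT4G04460 by 2.27 ± 0.36 and scpl48, a serine carboxypeptidase-like gene, by 1.96 ± 0.34. Of 3 xylem markers 1 rose, the xylan gene IRX15, by 1.46 ± 0.37, and 2 did adjusted over the list alone. The stele markers LHW (0.04 ± 0.39) and PHV (0.65 ± 0.33) did not pass. Of 2 heat shock genes 1 rose, the immunophilin gene AT5G48570, by 2.09 ± 0.42. Of 4 cell cycle genes 0 passed, with 0 at an unadjusted p under 0.05, among them AUR1, a mitotic kinase, at 0.03 ± 0.38 and PRL, a replication licensing factor, at -0.17 ± 0.37. The shoot photosynthesis genes LHCB4.1 and RCA had differences of -0.97 ± 0.46 and -0.65 ± 0.35, which did not pass. Except for the xylem and auxin lists and the detoxification list, counts adjusted over the list alone were the same. Jasmonate, pathogen defence, aquaporin, nutrient uptake, endodermis, phloem and cytosolic ribosomal protein lists had 0 tested members.

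**Figure D2:**
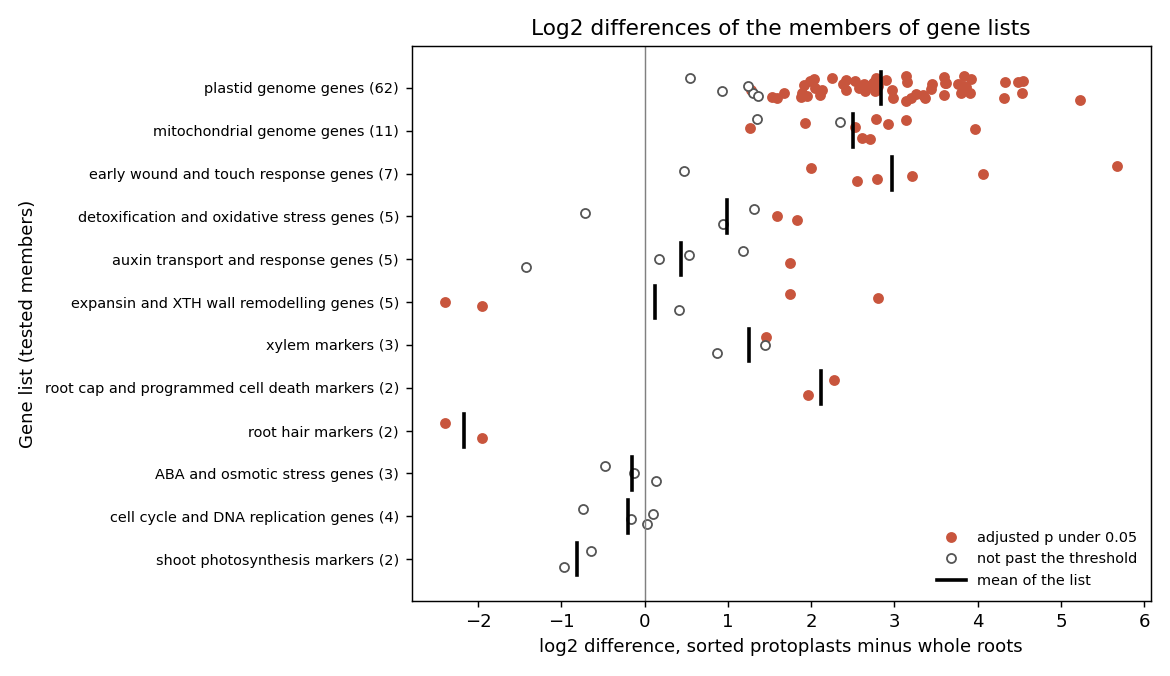
Log2 difference of sorted protoplasts minus whole roots (horizontal axis) for each tested member of 12 gene lists (vertical axis, with the number of members), filled where the adjusted p is under 0.05, with a black line at the list's mean. Plastid members centre on 2.83 and early wound and touch members on 2.97, the 2 root hair markers lie below 0, and no ABA and osmotic stress member is filled.

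The genes with a symbol that had the lowest differences were of several kinds. JAL22, a jacalin-related lectin gene, had a signal of 939 ± 637 in whole roots and 73.4 ± 68.1 in sorted protoplasts (SD, n = 2), a log2 difference of -3.48 ± 0.62 (SE, limma adjusted p = 0.00808). TRI, a tropinone reductase gene, had a difference of -3.01 ± 0.41, ATMYC1, a bHLH gene of the epidermis, one of -2.29 ± 0.38, and GPDHC1, a cytosolic glycerol phosphate dehydrogenase, one of -2.22 ± 0.36. EXPA18, given above, completes the 5. Among nuclear genes with a symbol the highest after JRG21 were WRKY22 at 4.1 ± 0.44, ZCF37 at 4.08 ± 0.68, CML38 and GRX480, a glutaredoxin gene, at 4.02 ± 0.41, a selection added after the organelle genes had been seen to fill the top.

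Over all 13647 probe sets, 870 were higher and 561 lower in sorted protoplasts in limma's test at an adjusted p under 0.05. Each of the 1431 differed by at least 1 on the log2 scale, since smaller differences could hardly pass with 2 arrays per group. The smallest differences called were 1.21 and -1.22. The median of the higher ones was 2.18 and that of the lower ones -1.65, both over probe sets selected by the same threshold. Without the probe sets of both organelle genomes 803 higher and 561 lower ones were left. The share of higher calls was 60.8% as deposited, 69.8% with array medians set equal and 39.0% with arrays scaled on hybridization spike-ins, a scaling chosen after seeing the data that moved the median log2 difference of all tested probe sets from -0.16 to -0.60. Without whole-root replicate 1 the calls were 192 higher and 54 lower, and without whole-root replicate 2 they were 167 and 25. Of the 30 named genes past the threshold, 7 stayed past it in both of these fits, rpl14, psaI, rpl36, AT1G76640, CML38, WRKY22 and GRX480. With spike-in scaling 6 named genes lost their call (AT5G48570, UGT73B4, CSLC04, LBD16, IRX15 and AT4G04460), and with no signal filter 10 did (JAL22, AT5G48570, UGT73B4, XTH18, LBD16, EXPA7, IRX15, ccb382, OSM34 and ZCF37). The ratio of 3' to 5' signal is used as a sign of RNA integrity, but after 2 cycles of amplification it need not reflect integrity alone. For GAPDH it was 15.0 and 4.56 on the whole-root arrays and 3.45 and 9.96 on the sorted-protoplast arrays. For this probe pair it differed more within groups than between them. In the same array order it was 22.16, 7.03, 8.51 and 11.96 for actin, and 2.49, 1.97, 2.21 and 1.98 for ubiquitin. Whole-root replicate 1 had the highest ratio for each of these genes. On a second GAPDH pair the 5' signal of whole-root replicate 1 was 612.38. The other whole-root array had 2064.74 there, and the sorted-protoplast arrays had 1876.15 and 1675.15.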

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

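One signal outside the comparisons is listed because the control probe sets were not part of the test, and it was looked at only after the main results had been seen. The 25S ribosomal RNA control was higher on both sorted-protoplast arrays (5388 and 9658) than on both whole-root arrays (4329 and 2809), with a log2 difference of 1.05 and a 95% interval from 0.14 to 1.95. The 5S ribosomal RNA control had a difference of -0.23, with a 95% interval from -1.40 to 0.94. The mean log2 signal of the 18 hybridization spike-in probe sets was 9.50 and 9.06 on the whole-root arrays and 9.40 and 10.04 on the sorted-protoplast arrays.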

How the results depend on the processing

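Scaling on spike-ins, the removal of organelle probe sets and the crossed replicate numbers were chosen after the data had been seen, and where a value moved the cause was not tested unless stated. The calls, 870 higher and 561 lower, became 394 and 137 with no filter (22746 probe sets tested), 393 and 107 at an adjusted p under 0.01, 236 and 37 in a test against a log2 difference of 1, both stricter by construction, and 397 and 620 with spike-in scaling. With 1 array left out, the number higher ranged from 167 to 989 and the number lower from 25 to 649, lowest without a whole-root array. Apart from the crossed replicate numbers, given below, the other settings stayed within 1.5 times. Of the 4 lists, 2 were called higher, against 1 with the replicate block and 0 with an estimated correlation or in fry. Those 2 tests leave means as they are: early wound and touch 2.97 and detoxification 0.99 (adjusted p = 0.274 and 0.0535 for each), plastid 2.83 (0.967 and 0.189) and mitochondrial 2.51 (0.967 and 0.275). With 1 array left out, the detoxification mean ranged from 0.80 to 1.19 and the auxin mean from -0.18 to 1.06.

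Replicates 1 and 2 share only a number, and the deviations of same-numbered samples correlated at -0.156 across probe sets. With the number as a replicate block the calls were 1123 higher and 787 lower, and the detoxification list (mean 0.99) had an adjusted p of 0.0518 and the LSM family one of 0.0527, and the block ended no other list or named-gene call. With crossed replicate numbers they were 1137 higher and 922 lower.

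For the 38 named genes, 595 comparisons with an alternative kept side and direction in 533, lost the call in 61, gained it in 1 (LHCB4.1 without sorted-protoplast replicate 1) and reversed in 0. Of the losses 20 came without whole-root replicate 1, 22 without whole-root replicate 2, 10 with no filter and 6 with spike-in scaling. The ABA and osmotic stress list reached 5 members with no filter (mean -0.15, camera adjusted p = 0.820). Low signal limits what can be seen: between 19.6% and 22.1% of values on an array were under the offset of 16.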

Other observations

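The lists named here and the tests on organelle transcripts and array scaling were chosen after the results had been seen. For neighbouring genes, only the test of pairs both higher and its filter on shared symbols or probes were set before their result. Of 7 tested calmodulin-like (CML) genes 4 rose, AT1G76640, CML38, CML37 at 3.03 ± 0.38 and CML23 at 2.30 ± 0.49, and CML43 had a difference of -0.62 ± 0.34, which did not pass. The family passed camera's test among the 39 added lists (adjusted p = 0.000256). That call was lost with an estimated correlation (adjusted p = 0.967) and in fry (adjusted p = 0.0716). AT1G76640 and CML38, its members with the largest rises, also belong to the early wound and touch list, so the 2 lists are not separate evidence. Of 13 nuclear genes with an osmotic, drought, salt, cold or abscisic acid name, 2 rose (STZ and COR27, the latter by 1.36 ± 0.36) and 1 fell (OSM34, an osmotin-like gene, at -2.13 ± 0.51), with a mean of -0.0037 and a median of -0.13, and camera, which gave the opposite sign, did not call the list (adjusted p = 0.953). Of 6 WRKY genes 2 rose, WRKY22 and WRKY53, and the family did not pass (adjusted p = 0.0644). The 6 LSM genes, whose proteins bind RNA in decapping and splicing complexes, were called lower as a family (mean -1.10, adjusted p = 0.0405), with LSM1A at -1.95 ± 0.37 the only member past the threshold. That call was lost with the estimated correlation of 0.810 (adjusted p = 0.967), in fry (adjusted p = 0.275) and without whole-root replicate 1 (mean -0.72). Each of the 6 genes had a higher signal on whole-root replicate 1 than on whole-root replicate 2. Whole-root replicate 1 also had the highest ratios of 3' to 5' signal given above, and whether this contributed was not tested. Over the family's alternatives the adjusted p ranged from 0.00337 to 0.967. None of the other added lists but the organelle ones passed camera's test.

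Shoot tissue in the sorted samples, as the whole cause of the higher plastid transcripts, would bring nuclear photosynthesis transcripts too. But 11 such genes, measured without the signal filter and without the brightest of their kind, which are unnamed here, had a mean log2 difference of -0.68. Its 95% interval, -1.02 to -0.33, was taken across the 11 genes and leaves out the spread between arrays. The mean lay below the plastid lower quartile of 2.06. An equal rise of all RNA without poly(A) tails, as the whole cause, would raise ribosomal RNA as much. The 25S control differed by 1.05, with an interval that ends below that quartile. But it was brighter in whole roots (4329 and 2809) than any plastid gene. The plastid gene nearest it there, atpE (2888), rose by 1.60, inside the 25S interval. Within each group the 25S signal and the plastid mean were higher on the same array. The 25S control alone therefore cannot set this cause aside. The 5S control, dim in whole roots (137.5 and 38.2), differed by -0.23. Another array scaling left the plastid mean at 2.39 or more, and leaving out either sorted-protoplast array left it at 2.31 or more. These tests were set on plastid genes, and the mitochondrial mean of 2.51 was 2.07 with spike-in scaling and 1.70 without sorted-protoplast replicate 2. Unequal priming of organelle RNA during amplification, loss of nuclear transcripts during digestion and a larger share of organelle-rich cells may each contribute and were not tested, and the design does not separate them from the preparation itself.

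The excess of higher over lower calls may come from array scaling: with spike-in scaling 39.0% of the calls were higher, against 60.8% as deposited. The spike-ins depend on the amount of labelled RNA put on each array, which is not known here, so neither split is taken as the true one.

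A hypothesis set before its test was that neighbouring nuclear genes rise together. Among 2181 pairs of adjacent protein-coding genes with both tested, 21 were both called higher, against a mean of 6.45 when calls were shuffled among the 7220 genes (one-sided permutation p = 0.0001, the smallest that 10000 shuffles can give, adjusted p = 0.0002 over 6 counts). For pairs both called lower, for which no expectation was written down, the count was 8 against 3.54 (one-sided permutation p = 0.026, adjusted p = 0.026). Without genes in the nuclear copy of the mitochondrial genome on chromosome 2, a count added after the pairs were seen, 19 pairs were both higher against 6.44. Duplicated genes of one family may account for the excess: without pairs that share a family symbol or a shared-probe set 18 pairs were left, 2.88 times the shuffled mean, but 0 of these 18 had a family symbol for both genes, so the filter could not see most families and the explanations cannot be told apart for these pairs. Examples of pairs outside named families, chosen after their values were seen, are AT2G26380 and AT2G26390 (5.03 and 2.93) and WRKY22 (4.1) with AT4G01240 (2.21).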
